A study of Solanum virginianum with 36 samples.

How the data were processed

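RNA was measured in 36 leaf libraries of eggplant, from a thrips-resistant and a thrips-susceptible line sampled at 0, 4, 8, 12, 24 and 48 h of feeding by western flower thrips, a cell-sucking insect pest. Each of the 12 groups held 3 libraries, which the labels call biological replicates. The organism label reads Solanum virginianum, a wild relative of eggplant, while the series speaks of eggplant. Per the labels' protocols, plants grew in a greenhouse under a photoperiod of 16 h light, total RNA was extracted from leaf and libraries were made with a SMARTER mRNA-Seq kit. Later libraries without feeding are not among the groups of the labels, so feeding and the hour of the day changed together. The libraries at 24 and 48 h would share the hour of those at 0 h.

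The authors deposited a table of whole-number estimated counts per gene ID and a table of FPKM values, with 1 column per library in each. FastQC and HTSeq 0.6.1 are named in the submitters' processing notes. The aligner, the genome build and the tool that made either table are not named in the sources used here, beyond the prefix Sme2.5 of the gene IDs. The design fixed before the data were examined took the whole numbers for read counts, and the values contradicted that. For 6744 IDs with a stable ratio of FPKM to deposited value (within 0.05 on the natural log scale), the FPKM gave the value before rounding. A deposited value of 1 stood for a median of 0.25 and a value of 2 for a median of 1.49. Of all values from 1 to 5 in these IDs, 93.8% lay between the whole number below and the value itself. No deposited value of 0 had an FPKM above 0. The table was therefore treated as estimated counts rounded up by the authors' processing, and a deposited value of 1 is not 1 read. The estimated counts were used as whole numbers, as deposited, with the test that had been fixed.

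The table had 89388 rows, of which 3945 carried no gene ID. These rows held 4.46 to 7.28% of the counts of a library and stayed out of library sizes and tests. Of the 85443 IDs, 33340 had a count in the series. Totals over rows with an ID were 30629392 to 42391553 per library. The deposited FPKM table held 65535 rows, which were the first 65535 rows of the count table in the same order. The other 23853 rows, with 25.6% of the counts with an ID, had no FPKM. The files do not pair the IDs with gene names or descriptions. For that reason, none of the 34 gene lists fixed before the data were examined was tested.

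Calculations were made in R 4.3.3. The main test was the quasi-likelihood test of edgeR 4.0.16 on all 36 libraries, with 1 mean per group, TMM normalization, the filterByExpr filter and Benjamini-Hochberg adjustment within each comparison at a threshold of 0.05. The filter left 23719 genes, with 99.97% of the counts with an ID. Comparisons were made between lines at each time, between each later time and 0 h in each line, and between lines in the change at each time (an interaction). An F-test over the 5 interactions tested the whole time course. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. CPM are the estimated counts scaled to the normalized library size in the usual unit of that name. The floor for a group of libraries without a count was 3 counts over all 18 libraries of a line. Floors cover counting error only and are in units of estimated counts.

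The rule for named genes, fixed before the data were examined, falls back on IDs where genes have no descriptions. Under it, the 2 IDs that rose and the 2 that fell most were named, applied per kind of comparison, among IDs past the threshold with at least 5 CPM in the higher group and, except for the interaction, no overlap between the groups compared. Alternatives fixed beforehand were the size factors of DESeq2, no filter on low counts, DESeq2 1.42.0, fits of only the groups compared, both forms of a replicate block, limma 3.58.1 on log2(FPKM + 1), and fits without each library in turn. A fit without IDs that were on and off within a group, a fit without the 8 and 12 h libraries, limma on FPKM scaled by TMM, the list of IDs without counts without each resistant library in turn and the contrasts that average times were chosen after seeing the data. Replicates differed by far more than sampling noise, with a chi-square per gene of 39 to 241 between libraries of a group, so each counted as 1 sample.

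The tests were tested on simulated data, with counts drawn for all 23719 genes and 200 genes changed in the resistant line at 4 h. For the change at 4 h against 0 h in that line, edgeR recovered 34% of the genes changed 2-fold and 76% of those changed 4-fold, with 3 false calls. For the interaction at 4 h it recovered 10% and 53%, with 3 false calls. For the time course it made 2 false calls. DESeq2 recovered 46% and 82% for the change at 4 h, with 46 false calls. It made 47 false calls (34% of its calls) for the interaction and 56 (36%) for the time course. Many more than 200 genes passed in the real comparisons between lines and against 0 h, and the adjusted threshold depends on that number. The recovered shares therefore do not carry over to those comparisons.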

Results

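Leaf RNA of a thrips-resistant and a thrips-susceptible eggplant line was sequenced at 6 times of thrips feeding, with 3 libraries per line and time. Estimated counts over rows with a gene ID came to 30629392 to 41243395 per library in the resistant line. In the susceptible line they came to 34360637 to 42391553. A count was found for 21910 to 23169 IDs per library in the resistant and for 23867 to 25077 in the susceptible line. Values are estimates rounded up to whole numbers, and the files give IDs without gene names, so IDs are reported as deposited and without a known function.

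The lines stood apart in every library. The first principal component of log2 CPM held 54.8% of the variance, with the resistant libraries at -152 to -121 and the susceptible ones at 133 to 147. The second held 6.19%. Correlations of log2 CPM across genes were 0.941 to 0.969 between replicates of a group and 0.787 to 0.844 between lines.

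**Figure D1:**
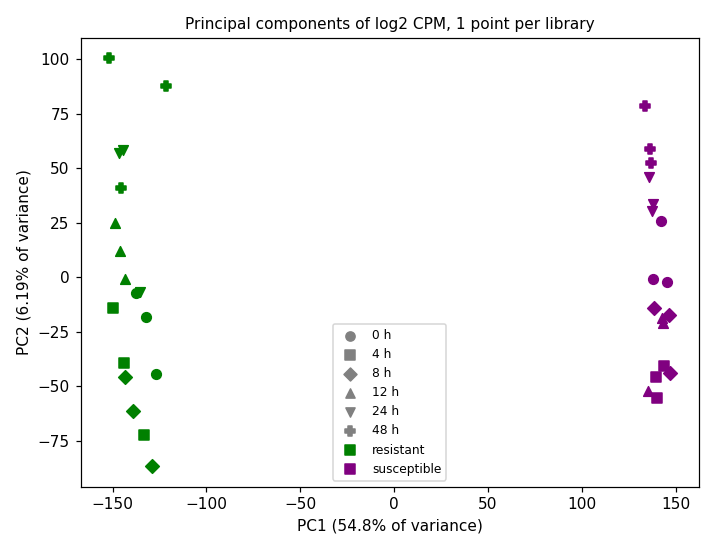
Principal components 1 (x axis) and 2 (y axis) of log2 CPM, in arbitrary units, with 1 point per library, colour for the line and shape for the time of feeding. The 18 resistant libraries lie at -152 to -121 on the first component and the 18 susceptible ones at 133 to 147.

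The first question was how the lines differ before and during feeding. Sme2.5_03222.1_g00003 had 138 ± 28.2 CPM (SD, n = 18) in the resistant line and no count in the susceptible line, so it was at least 31000-fold higher against a floor of 3 counts over the 18 libraries. Sme2.5_00085.1_g00028 had 1270 ± 381 CPM (SD, n = 18) in the resistant line and a deposited value of 1 or 2 in each susceptible library. In the other direction, Sme2.5_02311.1_g00006 had no count in the resistant line and 48.0 ± 46.4 CPM (SD, n = 18) in the susceptible line, at least 10000-fold higher. Its susceptible 0 h libraries ranged from 21.7 to 227 CPM. Sme2.5_13599.1_g00003 was also without a count in the resistant line, with 29.1 ± 9.27 CPM (SD, n = 18) in the susceptible line, at least 6200-fold higher. These bounds are in estimated counts and cover counting error only. An ID that a line lacks, or that diverges from the reference there, would also have no count, which stayed open as described below. All 4 IDs passed edgeR's quasi-likelihood test at each of the 6 times, which the rule for naming them required. Their adjusted p in that test at 0 h, also subject to the rule, ranged from 2.2e-24 to 8.8e-07.

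At 0 h, 8218 of 23719 genes differed between lines, 3617 higher and 4601 lower in the resistant line. The counts were 9817 at 4 h, 10141 at 8 h, 10596 at 12 h, 9298 at 24 h and 10028 at 48 h. Of these, 43.2 to 46.1% were higher in the resistant line, while limma on FPKM as deposited put more genes higher than lower at 0 h (51.1%) and 4 h (52.7%). With FPKM scaled by TMM, an alternative added after the result was seen, these shares were 44.1% and 46.1%, near those of the main test. In the same direction at all 6 times, 4050 genes differed, 1571 higher in the resistant and 2479 higher in the susceptible line. That count needs a separate call at each time, with 3 against 3 libraries. The line difference averaged over the 6 times, a contrast chosen after seeing the data, passed edgeR's test for 16359 genes (69%). Of those, 7647 were higher and 8712 lower in the resistant line. Among the 17979 genes that passed at any time, 877 passed in opposite directions at different times. At most 3 counts over the resistant line and at least 1 CPM in the susceptible line were found for 336 IDs, 238 of them without any count. This list was cut by replicate 3 at 48 h, described below, since without that library it held 500 IDs, 419 of them without any count, against 337 to 343 IDs without any other resistant library. The reverse held for 148 IDs, 129 of them without any count. With 6 libraries in a comparison, each fit of only the groups compared gave fewer genes, and 2381 then differed in the same direction at all 6 times.

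**Figure D2:**
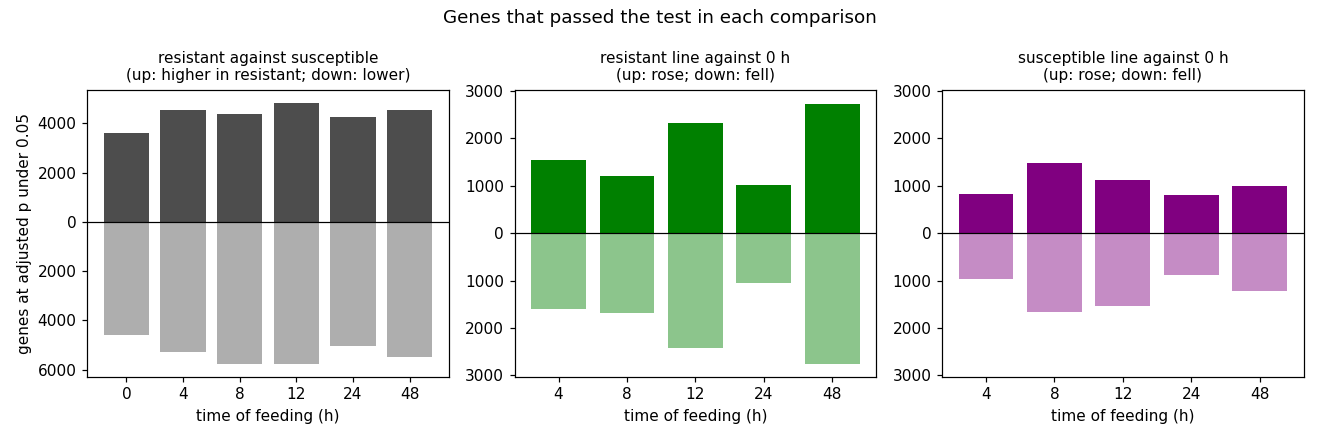
Genes at an adjusted p under 0.05 (y axis, number of genes) by hours of feeding (x axis), for the resistant against the susceptible line and for each line against its own 0 h libraries. Bars above 0 are genes that were higher or rose and bars below 0 are genes that were lower or fell. In the resistant line 5482 genes changed at 48 h, and 2785 in the fit of only the groups compared.

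The second question was what changed during feeding in the resistant line. Sme2.5_02389.1_g00012 rose from no count at 0 h to 18.8 ± 2.28 CPM at 4 h (SD, n = 3; edgeR adjusted p = 3.6e-02). At 8 to 48 h each group of the resistant line again held at least 1 library at 0 for this ID, and 5 of 15 alternatives ended the call. Sme2.5_24471.1_g00001 rose from no count at 0 h to 12.2 ± 0.897 CPM at 48 h (SD, n = 3; edgeR adjusted p = 4.5e-03), with 1 library at 0 at each of 4 and 12 h. In the susceptible line this ID also went up, from 0.563 ± 0.976 CPM at 0 h to 13.3 ± 1.95 CPM at 48 h (SD, n = 3). Sme2.5_00235.1_g00002 fell from 9.71 ± 10.7 CPM at 0 h to no count at 12 h (SD, n = 3; edgeR adjusted p = 3.7e-03), while its means in the susceptible line were 236 to 802 CPM. Sme2.5_00658.1_g00002 fell from 7.57 ± 6.39 CPM to no count at 48 h (SD, n = 3; edgeR adjusted p = 1.7e-04), with 1 library at 0.2 CPM at 0 h and 1 at 0 at 12 h. Of the 9 IDs named for a change over time or an interaction, 8 had at most 3 counts in 1 library and at least 5 CPM in another of the same group, and only Sme2.5_25219.1_g00001 did not.

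Against 0 h, 3144 genes changed at 4 h in the resistant line, with 1542 that rose and 1602 that fell. At 8 h 2895 changed (1215 rose), at 12 h 4744 (2314 rose), at 24 h 2064 (1017 rose) and at 48 h 5482 (2727 rose). The direction of the changes depended on the scale. Limma on FPKM as deposited, without TMM factors, gave 2098 that rose and 865 that fell at 4 h, 2004 and 895 at 8 h, 1949 and 1653 at 12 h, 493 and 1517 at 24 h, and 1166 and 3360 at 48 h. The median change of 12458 genes with a mean FPKM of at least 1 then stood at 0.11, 0.16, 0.00, -0.15 and -0.18 (log2). With FPKM scaled by TMM, an alternative added after the result was seen, 43 to 51.4% of the changed genes rose. At any later time, 9460 genes (39.9% of those tested) passed. These counts depended on the fit and on single libraries. Fits of only the groups compared gave 871, 1216, 4119, 762 and 2785 from 4 to 48 h. With 1 library left out the range was 1685 to 3816 at 4 h, 1899 to 2761 at 8 h, 2915 to 4120 at 12 h, 1169 to 2247 at 24 h and 3038 to 5497 at 48 h. Replicate 3 at 48 h held counts for 144 of 202 IDs that were otherwise nearly absent from the line and had at least 5 CPM in the susceptible line, at a median of 1.49% of the susceptible level. Without that library, 4339 genes changed at 48 h.

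In the susceptible line, Sme2.5_03245.1_g00008 rose from 0.0490 ± 0.0849 CPM at 0 h to 27.9 ± 18.9 CPM at 48 h (SD, n = 3; edgeR adjusted p = 5.9e-03), and 1 library at 4 h stood at 178 CPM beside 2 libraries at 0. Sme2.5_00597.1_g00008 rose from 0.0264 ± 0.00167 to 15.1 ± 16.5 CPM at 48 h (SD, n = 3; edgeR adjusted p = 4.6e-02). Its 0 h libraries each held a deposited value of 1, so the SD at 0 h reflects library size and not expression. Its 48 h libraries were at 0.0318, 32.8 and 12.4 CPM, and 6 of 12 alternatives ended the call. Sme2.5_04919.1_g00005 fell from 1460 ± 345 CPM to 0.0146 ± 0.0127 CPM at 8 h (SD, n = 3; edgeR adjusted p = 2.1e-02) and was at 2010 ± 706 CPM at 48 h, and 3 of 14 alternatives, those without 1 of the 8 h libraries, ended the call. Its 8 h libraries held deposited values of at most 1, so that mean and SD lie at the floor. Its libraries at 24 h were at 0.0887, 1090 and 0 CPM. Sme2.5_25219.1_g00001 fell from 18.3 ± 6.65 CPM to no count at 4 h (SD, n = 3; edgeR adjusted p = 2.5e-06) and was at 37.3 ± 14.6 CPM at 8 h.

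Against 0 h, 1808 genes changed at 4 h in the susceptible line, with 833 that rose and 975 that fell. At 8 h 3149 changed (1475 rose), at 12 h 2655 (1115 rose), at 24 h 1671 (797 rose) and at 48 h 2209 (996 rose). Limma on FPKM as deposited gave 1454 that rose and 550 that fell at 4 h, 2932 and 874 at 8 h, 1684 and 967 at 12 h, 584 and 883 at 24 h, and 578 and 1627 at 48 h. Median changes were 0.11, 0.20, 0.11, -0.02 and -0.12 (log2), and with FPKM scaled by TMM 45.4 to 51.2% of the changed genes rose. Fits of only the groups compared gave 1141, 986, 2182, 809 and 1480 from 4 to 48 h, and at 8 h 333 rose and 653 fell in that fit. At any later time, 6268 genes (26.4%) passed. Counts of each line do not show that the lines differ in response, which the interaction tests. With 1 library left out the range was 1007 to 1368 at 4 h, 1697 to 3015 at 8 h, 1739 to 2221 at 12 h, 900 to 1606 at 24 h and 1196 to 1941 at 48 h.

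**Figure D3:**
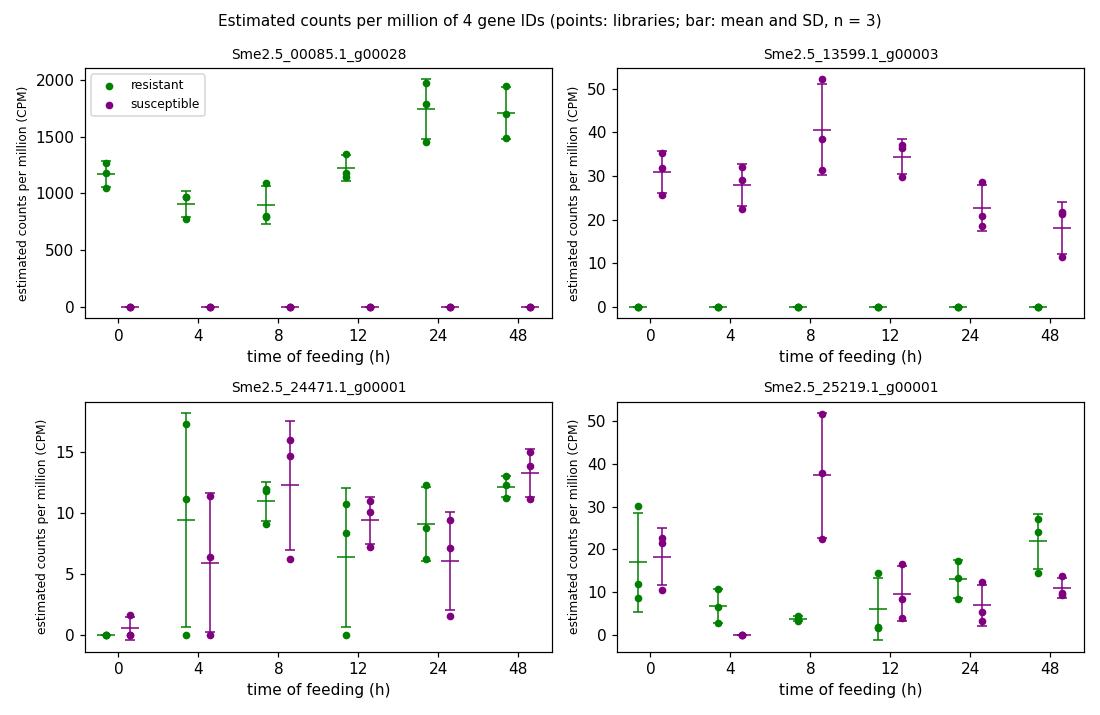
CPM (y axis) of 4 IDs by hours of feeding (x axis), with points for libraries and bars for the mean and SD of 3 libraries, coloured by line. Sme2.5_25219.1_g00001 had no count in any susceptible library at 4 h and 37.3 ± 14.6 CPM at 8 h.

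The changes of both lines were then set side by side at matched times, which share no library. Both lists came from 1 fit with a shared estimate of spread per gene, so genes of low spread pass more easily in both. The numbers for independent lists do not allow for this. At 24 h, 363 genes rose in both lines where independent lists would share 34.2, and 425 fell in both where 38.6 would be shared. At 4 h, 332 rose and 501 fell in both, against 54.2 and 65.9. At 8 h it was 397 and 728 against 75.6 and 119, at 12 h 557 and 849 against 109 and 158, and at 48 h 566 and 784 against 115 and 141. Genes that passed in both lines in opposite directions numbered 5 at 4 h, 20 at 8 h, 31 at 12 h, 4 at 24 h and 10 at 48 h. Across 18138 genes with a mean of at least 1 CPM, which are not independent replicates, the fold changes of both lines had Pearson correlations of 0.29 to 0.38. Spearman correlations were 0.35 to 0.52.

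The last question was whether the change over time differed between lines. Sme2.5_25219.1_g00001 differed at 4 h, with no count in the susceptible line and 6.75 ± 3.95 CPM in the resistant line (SD, n = 3; edgeR adjusted p of the interaction 2.8e-03), and 3 of 22 alternatives ended the call. Sme2.5_00658.1_g00002 differed at 48 h, with no count in the resistant line and 8.34 ± 2.02 CPM in the susceptible line (SD, n = 3; edgeR adjusted p of the interaction 1.6e-02), and 4 of 21 alternatives ended the call. For these 2 IDs the fit of only the groups compared was among them (edgeR adjusted p = 6.5e-02 and 1.4e-01). So was limma on FPKM as deposited (limma adjusted p = 1.2e-01 and 3.0e-01). Sme2.5_00235.1_g00002 at 12 h had an edgeR adjusted p of the interaction of 4.6e-02, and 12 of 18 alternatives ended that call. Sme2.5_24436.1_g00001 at 8 h had 4.7e-02 by the same edgeR test. That value rested on 1 resistant library at 86.1 CPM beside others at 0.387 and 0.0460 and on 1 susceptible 0 h library at 69.9 CPM beside others at 2.80 and 0.245, and 15 of 20 alternatives ended it.

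The interaction passed for 64 genes at 4 h, 299 at 8 h, 405 at 12 h, 54 at 24 h and 171 at 48 h. The F-test over all 5 later times passed for 3410 genes, and for 2146 to 4611 with 1 library left out. Without the 8 and 12 h libraries, and so over 3 later times, it passed for 450. The difference between 8 and 12 h correlated between lines, across 18138 genes, at -0.086, against 0.072 to 0.51 for the other 14 pairs of times. Counts for the interaction depended on single libraries. With 1 library left out they ranged from 23 to 555 at 4 h, 112 to 389 at 8 h, 147 to 383 at 12 h, 34 to 111 at 24 h and 52 to 488 at 48 h. The fit of only the groups compared gave 6, 57, 679, 16 and 22.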

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

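The tests of reads counted for rows without an ID or for another ID, of a plant carrying genes of the other line, of IDs without a count in the resistant 48 h replicate 3, of exchanged labels and of redrawn line labels for the interaction, in the form given below, were chosen only after the result was seen. The difference in response between lines was tested directly and passed edgeR's test for 64 genes at 4 h, 299 at 8 h, 405 at 12 h, 54 at 24 h and 171 at 48 h, and for 3410 genes over the time course. These counts depended on single libraries. With 1 library left out they ran from 23 to 555 at 4 h, 52 to 488 at 48 h and 2146 to 4611 over the time course. For 4 IDs the interaction, in fitted log2 units that depend on the prior count where a group is at 0, was 15.57 (Sme2.5_24436.1_g00001 at 8 h), 11.06 (Sme2.5_25219.1_g00001 at 4 h), -12.19 (Sme2.5_00235.1_g00002 at 12 h) and -11.00 (Sme2.5_00658.1_g00002 at 48 h). Rows without a gene ID were outside the comparisons, held at least 4.46% of the counts of each library and gave 1601 of 3297 tested rows that differed between lines at 0 h, 485 higher and 1116 lower in the resistant line.

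Line labels were also redrawn within each time in 100 splits, the real one included, with limma on log2 CPM. For the interaction and the time course, the mean of each line over its libraries was first set to the mean of all, since the line difference otherwise enters each redrawn interaction. In each case 1 of 100 splits, the real one, gave as many genes as the labels. The counts were 119 at 4 h (highest other 22), 367 at 8 h (175), 615 at 12 h (33), 92 at 24 h (28), 263 at 48 h (71) and 3839 over the time course (922). The difference in the same direction at all 6 times, without that step, gave 4250 (highest other 0). Redrawn groups there mixed the 2 lines, so a count near 0 was set in advance and this comparison cannot weigh chance. For the interaction and the time course, a chance division of the libraries reached the real count in fewer than 1 in 20 splits. Line differences that vary over time stayed in the redrawn groups and can lower their counts, so chance is argued against but not excluded. The splits do not address the dependence of the counts on single libraries. For the 16 comparisons of 3 with 3 libraries, 10 splits exist and 1 gave as many genes in each, a number too small for a share under 0.05. In 6-library edgeR fits the real split gave 5762, 7353, 7316, 9985, 6816 and 8028 genes between lines from 0 to 48 h, and the highest other split gave 1 each time. It gave 871, 1216, 4119, 762 and 2785 in the resistant line (highest other 1, 1, 2, 3 and 2) and 1141, 986, 2182, 809 and 1480 in the susceptible line (6, 1, 3, 3 and 6). Between lines, each other split mixed the 2 lines, so a count near 0 was set in advance. The other splits over time mixed the 2 times in the same way. Their low counts therefore do not weigh chance.

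The 8 and 12 h libraries did not order alike in both lines. The correlation between lines of the 8 to 12 h difference was -0.086 (-0.14 to 0.031 with 1 library left out). Exchanged labels in 1 line could not be told apart, since 3 of the 6 susceptible 8 and 12 h libraries correlated more with the resistant mean of the other time. With the gene loadings of the 2 main components of variation within groups removed, the correlation was 0.12, between the bounds set beforehand, against 0.18 to 0.47 for the other pairs. A shared axis between replicates may therefore contribute, and a difference in pace between the lines stays open and untested.

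Resistant 48 h replicate 3 held genes of the susceptible line at a low level. Over 202 IDs the median was 1.49% of the susceptible level, and in each of the other 35 libraries the corresponding median was 0. A plant that carries genes of the susceptible line is argued against, since 0 of the 202 IDs reached 0.5 of that level. RNA of the other line mixed into that library may account for the 144 IDs with a count, but 58 had none, and of 41 IDs that would have at least 5 counts at this share of the lowest susceptible level 5 had none where sampling would leave 0.043. Mixing therefore stays open, as do reads assigned to the wrong library.

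In 550 of the tested genes (2.32%), among them 8 of the 9 IDs named for a change over time or an interaction, 1 library of a group had at most 3 counts while another had at least 5 CPM. Reads counted for the neighbouring ID are argued against as the general cause, since the median share of the lost CPM that neighbours gained was 0 (95% bootstrap interval 0 to 0) over 464 genes, although it was between 0.5 and 2 in 65 of them. Rows without an ID mirrored 7.64% of the genes, under the highest of 20 shuffles (8.18%). Other IDs mirrored 27.1%, above the highest shuffle (24.5%), so estimates that move between IDs may account for a small part. Real differences between plants stay open.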

How the results depend on the processing

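Counts for all 23 comparisons stayed within 1.5 times of the reported ones with the size factors of DESeq2, without the filter, with the replicate block and, chosen after seeing the data, without genes on and off within a group. The replicate numbers did not pair the libraries: in 0 of 16 group pairs was each same-number correlation over 0.1, and 20 of 48 libraries correlated best with their own number. The replicate block gave 8243 genes between lines at 0 h, and a replicate block within each line gave 288 for the interaction at 48 h, the 1 count it moved by more. DESeq2 gave 2799 and 2574 genes for the susceptible line at 4 and 24 h, 532, 990, 1317, 354 and 890 for the interaction from 4 to 48 h, and 6651 for the time course. In simulated data it made 47 false calls for the interaction at 4 h and 56 for the time course, against 3 and 2 by edgeR. Those data were drawn with edgeR's own dispersions and without a line difference. They therefore do not decide which tool is nearer the truth for the real counts. Fits of only the groups compared gave 871, 1216, 762 and 2785 for the resistant line at 4, 8, 24 and 48 h, 1141, 986 and 809 for the susceptible line at 4, 8 and 24 h, 6, 57, 679, 16 and 22 for the interaction, and 2381 for all 6 times. Limma on log2(FPKM + 1), with the genes of the shorter table, gave 183, 504, 732 and 113 for the interaction at 4, 8, 12 and 24 h and 2594 for all 6 times. With FPKM scaled by TMM, chosen after seeing the data, it gave 160, 680, 95 and 309 at 4, 12, 24 and 48 h and 2679 for all 6 times. On FPKM as deposited 5967 genes differed between lines at 0 h, 6297 with a pseudocount of 0.1 and 4349 with a mean FPKM of at least 1. Without the 8 and 12 h libraries, also chosen after seeing the data, the interaction gave 32, 35 and 73 at 4, 24 and 48 h and the time course 450. The cause of these shifts was not tested. Leaving out 1 library moved no count between lines by more than 1.5 times. For the resistant line at 4 h the range was 1685 to 3816, with 1920 without 0 h replicate 1, 1836 without 4 h replicate 2 and 1685 without 4 h replicate 3. For the resistant line at 8 h the range was 1899 to 2761, with 1899 without 0 h replicate 2 and 1926 without 8 h replicate 1. For the resistant line at 12 h the range was 2915 to 4120, with 2915 without 0 h replicate 1 and 3160 without 12 h replicate 2. For the resistant line at 24 h the range was 1169 to 2247, with 1367 without 0 h replicate 1 and 1169 without 24 h replicate 3. For the resistant line at 48 h the range was 3038 to 5497, with 3161 without 0 h replicate 1 and 3038 without 48 h replicate 2. For the susceptible line at 4 h the range was 1007 to 1368, with 1116 without 0 h replicate 3, 1099 without 4 h replicate 1 and 1007 without 4 h replicate 2. For the susceptible line at 8 h the range was 1697 to 3015, with 1697 without 0 h replicate 3. For the susceptible line at 12 h the range was 1739 to 2221, with 1739 without 0 h replicate 3 and 1753 without 12 h replicate 2. For the susceptible line at 24 h the range was 900 to 1606, with 900 without 24 h replicate 2. For the susceptible line at 48 h the range was 1196 to 1941, with 1462 without 0 h replicate 1, 1352 without 0 h replicate 3, 1436 without 48 h replicate 1 and 1196 without 48 h replicate 3. For the interaction at 4 h the range was 23 to 555, with 26 without resistant 0 h replicate 1, 555 without resistant 4 h replicate 1, 23 without resistant 4 h replicate 2, 23 without resistant 4 h replicate 3, 32 without susceptible 0 h replicate 2, 39 without susceptible 0 h replicate 3, 31 without susceptible 4 h replicate 2 and 25 without susceptible 4 h replicate 3. For the interaction at 8 h the range was 112 to 389, with 113 without resistant 0 h replicate 2, 176 without resistant 8 h replicate 1, 194 without resistant 8 h replicate 2, 178 without resistant 8 h replicate 3, 112 without susceptible 0 h replicate 3 and 150 without susceptible 8 h replicate 1. For the interaction at 12 h the range was 147 to 383, with 179 without resistant 0 h replicate 1, 162 without resistant 12 h replicate 2, 209 without resistant 12 h replicate 3, 222 without susceptible 0 h replicate 2, 147 without susceptible 12 h replicate 1 and 251 without susceptible 12 h replicate 3. For the interaction at 24 h the range was 34 to 111, with 104 without resistant 24 h replicate 1, 35 without resistant 24 h replicate 3, 111 without susceptible 24 h replicate 1, 35 without susceptible 24 h replicate 2 and 34 without susceptible 24 h replicate 3. For the interaction at 48 h the range was 52 to 488, with 76 without resistant 0 h replicate 1, 86 without resistant 0 h replicate 3, 488 without resistant 48 h replicate 1, 52 without resistant 48 h replicate 2, 103 without susceptible 0 h replicate 1, 80 without susceptible 0 h replicate 2, 84 without susceptible 48 h replicate 1, 110 without susceptible 48 h replicate 2 and 86 without susceptible 48 h replicate 3. For the time course the range was 2146 to 4611, with 2146 without susceptible 8 h replicate 1. The 16 values of named IDs had 258 values under alternatives, of which 210 kept their direction and side of the threshold, 48 kept the direction only and 0 reversed. The gene set alternatives were not run, since the files pair no ID with a description. Rounding up of the estimates limits what can be said of values of a few counts.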

Other observations

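The tests of averaged times and the neighbour test without single libraries were chosen only after the result was seen. The mean of 4, 8 and 12 h was set against the mean of 0, 24 and 48 h. In the resistant line 4996 genes passed edgeR's test, 2438 higher and 2558 lower at 4 to 12 h, and in the susceptible line 5846 passed, 3039 higher and 2807 lower. The mean of 24 and 48 h against 0 h, which would share an hour of the day, gave 4223 genes in the resistant line (1953 higher) and 2279 in the susceptible line (944 higher).

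The share of counts in rows without a gene ID was 4.62 ± 0.0769% (SD, n = 3) at 0 h in the resistant line and 5.44 ± 0.436% in the susceptible line. It was 5.22 ± 0.0145% and 6.04 ± 0.138% at 4 h, 5.23 ± 0.0805% and 6.84 ± 0.655% at 8 h, and 5.16 ± 0.0317% and 6.23 ± 0.301% at 12 h. At 24 h it was 4.57 ± 0.103% and 5.79 ± 0.243%, and at 48 h 4.57 ± 0.125% and 4.89 ± 0.157%.

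A hypothesis written before its test was that IDs without counts in 1 line lie in stretches that this line lacks or that diverge from the reference. The 336 IDs of the resistant line formed 6 neighbouring pairs where random sets gave 2.71 (one-sided permutation p = 0.057, 10000 sets), and the 148 of the susceptible line formed 2 where 0.554 were expected (one-sided permutation p = 0.11). Neither passed 0.05, with few pairs to judge from. A p of 0.05 or more had been set beforehand as counting against the hypothesis. The resistant list was cut by 48 h replicate 3, which held genes of the susceptible line. Without that library 500 IDs formed 18 pairs where 6.05 were expected (one-sided permutation p = 2e-04), while the p without any other resistant library was 0.058 to 0.068. By the bound set beforehand, the hypothesis was not borne out. It was left open only after these values were seen, since the outcome turned on 1 library and the susceptible line gave few pairs. Gene models split over neighbouring IDs could not be told apart from other reasons for neighbours to move together. Neighbours correlated at 0.103 of the same-gene correlation for the line difference and at 0.0909 to 0.101 for the change over time, a mean difference of 0.00693 that lay within the spread between replicates.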
